A study of Mus musculus with 9 samples.

How the data were processed

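RNA of mouse hippocampus was measured by RNA sequencing in 9 libraries from animals carrying the human amyloid precursor protein transgene hAPP-J20 (Tg) and non-transgenic animals (nTg). Per the labels' protocols, total RNA was extracted with the RareRNA kit (Genepure) and libraries were prepared with the KAPA mRNA HyperPrep kit (Roche). The groups were Tg at 24 weeks (3 libraries), Tg at 15 weeks (3), nTg at 24 weeks (2, replicates 1 and 3) and nTg at 15 weeks (1, replicate 2). Libraries are named below by genotype, age and replicate, as in Tg_24w_3. The labels call them biological replicates but do not say that each came from its own animal, so the p-values measure the spread between these samples, part of which may be technical. The labels give each library a batch, named 15w or 24w, that equals its age, so age and batch cannot be told apart. Whether this label marks separate processing or only restates the age is not known. The sex of the animals is not in the labels.

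The authors deposited whole-number read counts per gene, not normalized, in 1 column per library, and every count test below used them as deposited. The deposited TPM values, computed by the authors, were used for 1 alternative; FPKM sheets of the same libraries were not used. The submitters' processing notes name CASAVA, Trimmomatic 0.38, HISAT2 2.1.0, featureCounts 2.0.0, DESeq2 1.26.0 and the mouse build GRCm38, with no order or settings. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of a gene and of one overlapping it on the other strand are therefore not separable, and genes with near-identical copies are named as uncertain. All 55536 gene identifiers had the same identifier, start and end in GENCODE M21, from which coordinates were taken (1-based, GRCm38). Of these genes 2339 had no symbol in the deposited table and held 1.88% of all counts; 92 symbols belonged to more than 1 gene, and such genes were not named.

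Total counts ranged from 12733452 (Tg_24w_3) to 21529266 (Tg_15w_3), so that 1 CPM stood for about 12.73 to 21.53 counts. No pair of libraries held identical values. Chi-square per degree of freedom between pairs, over genes with at least 20 counts, lay between 9.11 and 80.7, far above sampling noise, so each library counted as 1 replicate.

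Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors, filterByExpr on the fitted groups) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter kept 17457 genes, and 19574 in the 4-group fit. Genotype was tested over all 9 libraries with age as an additive term. Tg at 15 weeks and Tg at 24 weeks were each tested against the 3 nTg libraries of both ages, and against one another, in 1 fit with 3 groups; the nTg libraries were pooled because 15-week nTg has 1 library. The interaction of genotype and age was tested in a fit with 4 groups, which also gave the change between ages in nTg, a value chosen after seeing the data. Log2 fold changes are given with standard errors, computed as the absolute log2 fold change divided by the square root of edgeR's F statistic. Group values are TMM-normalised CPM as mean ± SD.

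Gene lists were written down before the data were examined, as were the comparisons, the tests, most of the alternatives and the rule for named genes. There were 40 lists with 777 genes, of which 38 were tested and 2 (sex-linked genes, transgene locus) served only as checks. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) with Benjamini-Hochberg adjustment over the lists of a comparison. Beside each, camera was run with an estimated correlation and fry as a self-contained test. A list's median is that of its members' log2 CPM differences in this fit. List scores per library are the mean log2 CPM of the members. The scores, the lists scored and their permutation tests are not named in the plan fixed beforehand.

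The rule for named genes, for each of the first 4 comparisons, was as follows. App and Zbtb20 (the known insertion site of the J20 transgene), Xist and Y-linked genes were named throughout. Among genes past the threshold with a mean of at least 1 CPM, a symbol and no overlap between the compared groups, the 10 largest changes in each direction were named, leaving out predicted genes, pseudogenes and ribosomal protein genes. Where fewer than 5 genes passed, the 5 of smallest p were named instead. Up to 4 members of smallest p were taken from each list with a called test or a called member, and from the astrocyte and insulin lists, since the study's title concerns these. Genes named outside this rule are marked as chosen after their values were seen.

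The pipeline was tested on simulated data drawn from the real libraries' means and sizes, with 100 genes changed by 1 and 100 by 2 on the log2 scale. At a change of 1, 89% of genes were called in the genotype comparison (17366 genes simulated), 79% at 15 weeks (17365), 74% at 24 weeks (17376) and 75% between ages (17356). At a change of 2 the shares were 100%, 99%, 98% and 100%, with 12, 16, 8 and 9 false calls. The changed genes were drawn only from those with an average log2 CPM above 2. No simulated library lay apart, had a trend with GC content or held neighbouring tissue. The shares therefore do not say how many real changes of these sizes would be called. A simulated list of 25 genes shifted by 0.4 was called in each of the 4 comparisons and an unchanged list in 0. A call there was an unadjusted camera p below 0.05, and the genes were drawn independently of one another. The simulation therefore says nothing about calls of real lists, whose members can be correlated.

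The alternatives fixed at that time were RLE factors, DESeq2 1.42.0, no filter, a filter at 1 CPM in at least 3 libraries, a fold change of at least 1.5, each library left out in turn, a covariate of Xist against Y-linked expression, the replicate number as a block, age-matched controls, the spread from the compared libraries alone, no age term, the 24-week libraries alone and 4 groups. Chosen after seeing the data were a fit without 2 doubted libraries, an offset for each library's trend with GC content and transcript length (splines with 4 degrees of freedom, known for 17451 of the 17457 genes), limma voom with sample quality weights, limma on log2(TPM + 0.5), and the estimated correlation for lists against age-matched controls. The doubted libraries were Tg_24w_3, which lay apart on the first principal component and had the lowest total, and nTg_24w_1, in which Xist was counted beside Y-linked genes and choroid plexus markers were highest. Splits of the libraries used the same edgeR fits. Shared-control simulations used differences of mean log2 CPM, and their genes were those with the largest difference relative to its spread. Exact permutation tests were two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.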

Results

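Gene expression was measured by RNA sequencing in the hippocampus of hAPP-J20 mice (Tg), which express a mutant human amyloid precursor protein in neurons and deposit amyloid plaques with age, and of non-transgenic mice (nTg). The series set 15 weeks, before plaques, against 24 weeks, after plaques have formed. Its title concerns astrocytes, insulin and signals between brain and periphery. There were 3 Tg libraries at 24 weeks, 3 Tg at 15 weeks, 2 nTg at 24 weeks and 1 nTg at 15 weeks. Total counts were 20201207, 19277883 and 12733452 for Tg at 24 weeks and 17444752, 18880685 and 21529266 for Tg at 15 weeks. They were 16110279 and 16089966 for nTg at 24 weeks and 20126802 for nTg at 15 weeks. The batch given in the labels equals the age of each library, so the batch changes with age in each comparison between ages.

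The deposited counts hold mouse genes, so the human transgene has no entry of its own, and its reads can be counted in mouse App only where the sequences match. App (chromosome 16, 84949685 to 85173766, GRCm38) stood at 1540, 1459 and 803 CPM in Tg at 24 weeks and 1438, 1507 and 1496 CPM in Tg at 15 weeks. In nTg it stood at 1022 and 1449 CPM at 24 weeks and 1499 CPM at 15 weeks. The log2 difference of App between Tg and nTg was 0.02 ± 0.20 (SE, edgeR adjusted p = 0.99). App did not separate the genotypes, so the Tg and nTg labels could not be checked by the transgene and were taken as given. Zbtb20, the gene in which the J20 transgene is inserted (chromosome 16, 42875881 to 43642602), stood at 137, 141 and 514 CPM in Tg at 24 weeks and 205, 203 and 162 CPM in Tg at 15 weeks. In nTg replicates 1, 2 and 3 it stood at 245, 338 and 339 CPM. Its log2 difference between Tg and nTg was −0.42 ± 0.36 (edgeR adjusted p = 0.869). Without Tg_24w_3 it was −0.97 and passed the threshold (adjusted p = 0.0166, range over its alternatives 0.00622 to 1), and without nTg_15w_2 it was −0.15. Zbtb20 stood at −1.06 without both Tg_24w_3 and nTg_24w_1, −0.88 with voom, −0.64 with TPM, −0.2 with an offset for GC content and transcript length and −0.19 in the 24-week libraries alone.

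Xist, transcribed from the inactive X chromosome of females, and the Y-linked gene Ddx3y divided the libraries within groups. Xist stood at 82.9 CPM in Tg_24w_3, 114 CPM in Tg_15w_1, 48.5 CPM in Tg_15w_3 and 65.1 CPM in nTg_24w_3, each with Ddx3y at 0 CPM. Ddx3y stood at 28.1 to 57.3 CPM in the other 5 libraries. In 1 of these, nTg_24w_1, Xist was counted as well, at 7.33 CPM, against 0.05 to 0.15 CPM in the other 4. Whether nTg_24w_1 held RNA of 1 animal only is not settled by the counts, and it enters each comparison with nTg. The first principal component of log2 CPM held 37.1% of the variance and set Tg_24w_3 (84.6) apart from the other 8 libraries (−30.9 to 4.87). Markers of neighbouring tissue differed between libraries of 1 group. Each value is the median over the markers of a library's log2 CPM minus the median of the other 8 libraries. Choroid plexus markers stood at 1.05 in nTg_24w_1, 0.58 in Tg_24w_1, −1.08 in Tg_24w_2 and −1.09 in Tg_15w_3. Blood markers stood at 1.72 in Tg_24w_3 and 0.842 in Tg_24w_2. Markers of meninges and of peripheral myeloid cells stood at −0.872 and −1.01 in nTg_15w_2.

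**Figure D1:**
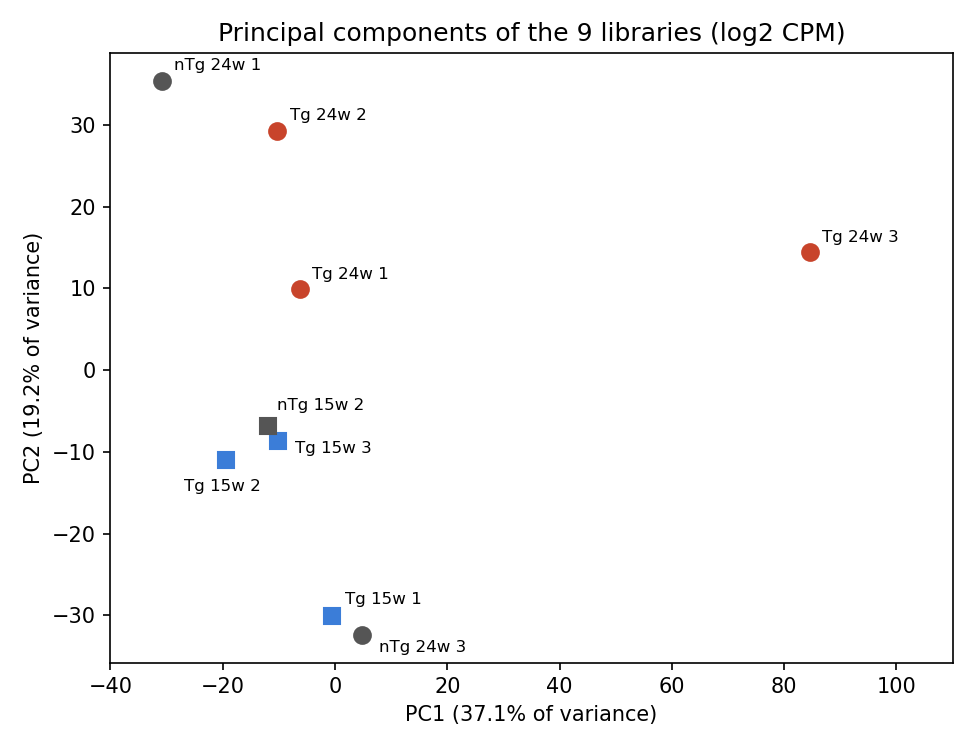
Principal components of log2 CPM of the 9 libraries, with PC1 (37.1% of variance) on the x axis and PC2 (19.2%) on the y axis; squares are 15 weeks and circles 24 weeks, grey nTg, blue Tg at 15 weeks and red Tg at 24 weeks. Tg_24w_3 lies at 84.6 on PC1, and the other 8 libraries lie between −30.9 and 4.87.

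The first comparison asked what differs between Tg and nTg hippocampus over both ages (6 against 3 libraries, with age as a term). Activity-regulated genes, which neurons transcribe after firing, fell as a list in Tg (camera adjusted p = 2.48e-17, but adjusted p = 0.145 with an estimated correlation). Fos, an immediate-early transcription factor, stood at 4.63 ± 2.21 CPM in Tg (SD, n = 6) and 15.3 ± 3.07 CPM in nTg (n = 3), a log2 difference of −1.94 ± 0.25 (SE). Arc, which regulates glutamate receptors at synapses, differed by −1.21 ± 0.18 and the nuclear receptor Nr4a1 by −0.96 ± 0.15. Dusp6, a phosphatase that inactivates ERK kinases, differed by −0.71 ± 0.12, and Drd1, the D1 dopamine receptor, by 1.21 ± 0.18. No single gene passed the threshold: edgeR's adjusted p was 0.0731 for Fos, 0.13 for Arc and Drd1, 0.136 for Nr4a1 and 0.197 for Dusp6. Of the 28 activity-regulated genes, 24 had a negative difference, with 0 past the threshold over all genes and 15 lower when adjusted over the list alone. Their median was −0.518, and camera's adjusted p ranged from 5.86e-19 to 0.145 over the alternatives. The test fry, which asks whether members move on balance in 1 direction and does not compare them with other genes, gave adjusted p = 0.0229.

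The mean log2 CPM of the activity-regulated list was 4.31 ± 0.14 in Tg (SD, n = 6) and 4.82 ± 0.17 in nTg (n = 3), lower in every Tg library than in every nTg library. An exact two-sided permutation test gave p = 0.0119, the smallest that 84 splits allow, and 0.0833 after Benjamini-Hochberg adjustment over 7 list scores. This test and the choice of the 7 lists are not named in the plan fixed beforehand. Within the 24-week batch the score differed by −0.59 (3 against 2 libraries), and within the 15-week batch by −0.45 (3 against 1).

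**Figure D2:**
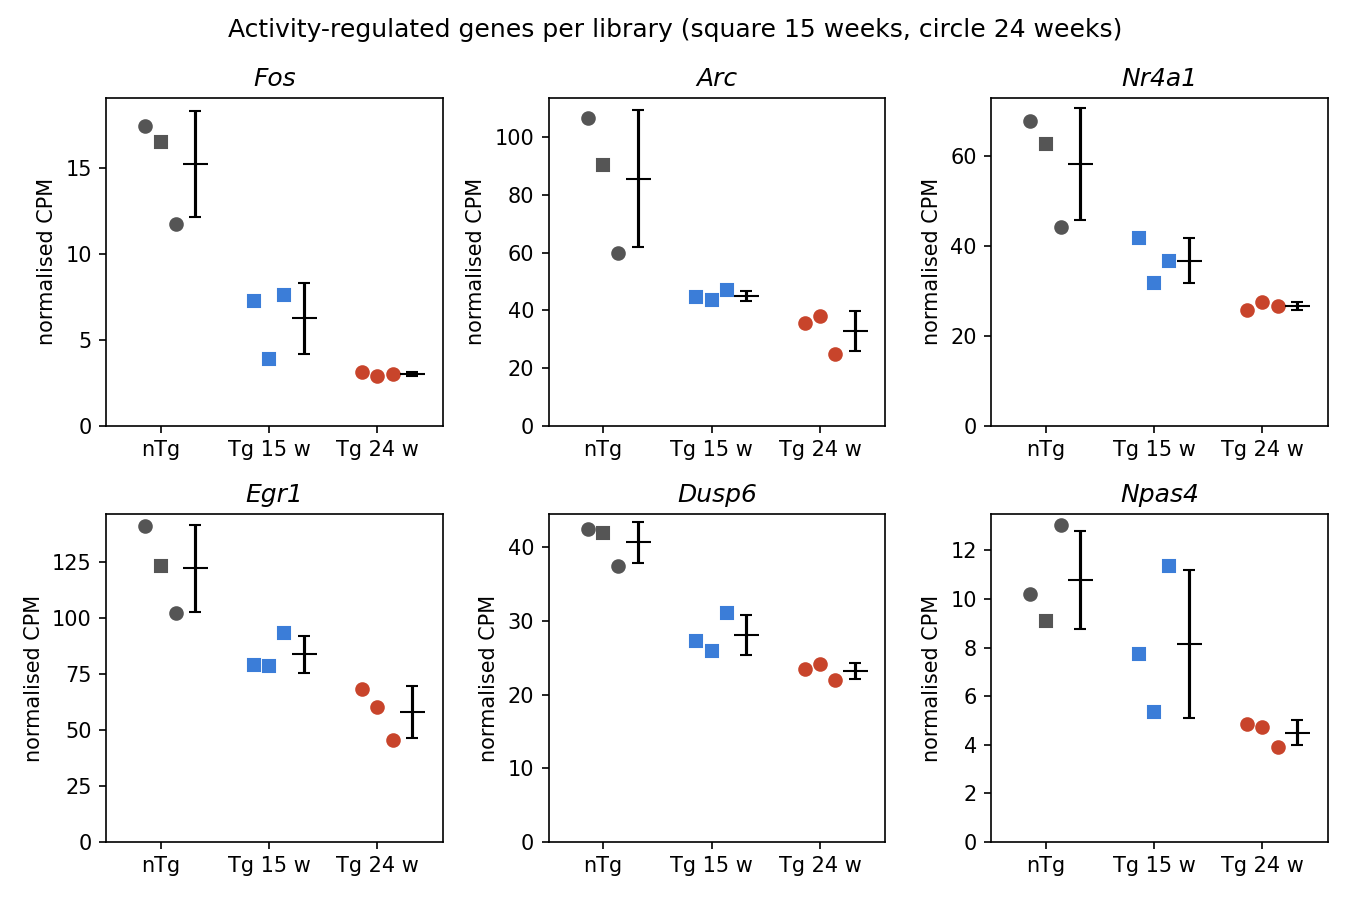
Normalised CPM (y axis, from 0) of 6 activity-regulated genes in nTg, Tg at 15 weeks and Tg at 24 weeks (x axis); each point is 1 library (square 15 weeks, circle 24 weeks), and the black bars are mean ± SD of 3 libraries. Fos lies between 2.87 and 7.62 CPM in Tg and between 11.74 and 17.48 CPM in nTg.

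The number of genes past the threshold between Tg and nTg was 0 of 17457 with edgeR, with 941 at an unadjusted p under 0.05 where chance gives 873. DESeq2 called 35, limma voom with quality weights 7 and limma on TPM 0, and edgeR called 5 without Tg_24w_3 and 4 without nTg_15w_2. In a fit of the 5 libraries of the 24-week batch alone (3 against 2), which also gave the spread, edgeR called 0, with 670 at an unadjusted p under 0.05. The 15-week batch has 1 nTg library.

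Of the 38 lists, camera called 6 as higher and 6 as lower in Tg over both ages. No list call in any comparison held with an estimated correlation, and in no called list did the median, the mean and camera's direction differ in sign. Counts of members past the threshold are given in pairs, first over all genes and then adjusted over the list alone. Cholesterol synthesis genes rose as a list, with a median of 0.281 and a positive difference in 21 of 23 members (0 and 0; adjusted p = 0.448 with an estimated correlation). Fdft1, squalene synthase, stood at 0.51 ± 0.15. Interferon response genes rose as a list by a median of 0.244, positive in 25 of 26 members (0 and 0; adjusted p = 0.448 with an estimated correlation), with Psmb9 of the immunoproteasome at 1.06 ± 0.30. Complement genes had a median of 0.326, positive in 12 of 15 (0 and 1 higher; adjusted p = 0.448 with an estimated correlation), with C4b at 0.60 ± 0.16. Reactive astrocyte genes had a median of 0.207, positive in 17 of 24 (0 and 0; adjusted p = 0.448 with an estimated correlation), with the intermediate filament gene Gfap at 0.51 ± 0.21. Gfap stood at 0.26 without nTg_24w_3 and 0.8 without nTg_15w_2, and C4b at 0.92 without nTg_15w_2. In the 24-week libraries alone Gfap stood at 0.77, and Fdft1 stood at 0.33 with voom and Psmb9 at 0.65 with TPM. Markers of meninges and fibroblasts had a median of 0.529, positive in 11 of 14 (0 and 2 higher; adjusted p = 0.463 with an estimated correlation), with the proteoglycan gene Dcn at 0.72 ± 0.16. Markers of peripheral myeloid and lymphoid cells had a median of 0.457, positive in 6 of 8 (0 and 1 higher; adjusted p = 0.448 with an estimated correlation), with the macrophage receptor Mrc1 at 0.78 ± 0.21 (0.5 with TPM). Meningeal and myeloid markers were those that stood at −0.872 and −1.01 in nTg_15w_2.

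Oligodendrocyte and myelin genes fell as a list in Tg, with a median of −0.289, negative in 18 of 20 members (0 and 0; adjusted p = 0.448 with an estimated correlation). Myelin basic protein, Mbp, stood at −0.47 ± 0.15. Markers of dentate gyrus granule cells fell as a list by a median of −0.35, negative in 13 of 18 (0 and 3 lower; adjusted p = 0.412 with an estimated correlation). Among them the desmosomal gene Dsp stood at −1.53 ± 0.27 and the transcription factor Prox1 at −0.65 ± 0.14. Choroid plexus markers had a median of −0.565, negative in 20 of 20 (0 and 0, adjusted p = 0.511 with an estimated correlation). Kl stood at −0.70 ± 0.28 (−0.42 without nTg_24w_1, −0.39 also without Tg_24w_3, −0.45 with voom). In nTg_24w_1 the choroid plexus markers stood 1.05 above the median of the other libraries. Ependymal markers had a median of −0.241, negative in 9 of 9 (0 and 0, adjusted p = 0.511 with an estimated correlation). In nTg_24w_1 they stood 0.818 above the median of the other libraries. Peripheral hormone and metabolic receptors had a median of −0.105, negative in 19 of 28 (0 and 0; adjusted p = 0.448 with an estimated correlation), with the adiponectin receptor Adipor2 at −0.39 ± 0.14 (−0.25 without nTg_24w_1, −0.62 without nTg_15w_2 and −0.65 in the 24-week libraries alone). The insulin and IGF signalling list was not called (median −0.067 and mean 0.001, camera adjusted p = 0.188), nor was the astrocyte list (median −0.018, adjusted p = 0.403). Over the alternatives the highest adjusted p of the 12 called lists lay between 0.145 and 0.748.

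Several of these calls over both ages were lost when 1 library was left out. Where the median changed little, the loss does not show that the call rested on that library. The reactive astrocyte call was lost without Tg_24w_1 (median 0.243), Tg_24w_3 (0.188), Tg_15w_1 (0.162), nTg_15w_2 (0.253) or nTg_24w_3 (0.205). The interferon call was lost without nTg_24w_3 (0.227). The ependymal call was lost without Tg_24w_2 (−0.08) or nTg_24w_1 (−0.169), and its median was −0.389 without nTg_15w_2 and −0.372 without nTg_24w_3. Without nTg_15w_2 the meningeal call was lost (0.371) and the myeloid median became −0.072. Hormone receptors lost their call without any library but Tg_15w_2, with medians of −0.129 to −0.081, and with an offset for GC content and transcript length (−0.064). With calls kept, medians moved by over 1.5 times for choroid plexus without Tg_24w_2 (−0.303), for granule cells without Tg_24w_3 (−0.229) or nTg_24w_3 (−0.176) or with the offset (−0.226), and for complement without nTg_24w_1 (0.165) or with the offset (0.162). Without both doubted libraries, Tg_24w_3 and nTg_24w_1, the complement (0.098) and hormone receptor calls (−0.084) were lost, and the reactive astrocyte median was 0.133.

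The second comparison set Tg at 15 weeks, before plaques, against nTg (3 against 3 libraries). Activity-regulated and myelin genes fell as lists by camera, with adjusted p = 0.33 and adjusted p = 0.439 with an estimated correlation. The genes of smallest p were Fos (−1.29 ± 0.25, SE), the myelin gene Opalin (−0.88 ± 0.18), Sox10, a transcription factor of oligodendrocytes (−0.85 ± 0.18), Galnt6 (−0.86 ± 0.19) and Arc (−0.93 ± 0.21). None of them passed the threshold (edgeR adjusted p = 1 for each). The number of genes past it was 0 of 17457, with 575 at an unadjusted p under 0.05 where chance gives 873. DESeq2 called 2, limma voom with quality weights 5 and limma on TPM 0. Against the nTg library of the same batch alone, edgeR called 0 with 185 at an unadjusted p under 0.05, a fit that assumes this 1 library to vary like the other groups.

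Of the 38 lists, camera called 3 as higher and 7 as lower at 15 weeks. Activity-regulated genes fell as a list by a median of −0.428, negative in 25 of 28 (0 over all genes and 12 lower adjusted over the list alone; camera adjusted p = 1.12e-13). The call gave adjusted p = 0.33 with an estimated correlation, and a range of 1.29e-15 to 0.33 over the alternatives. Oligodendrocyte and myelin genes fell as a list by a median of −0.411, negative in 18 of 20 (0 and 2 lower; adjusted p = 0.439 with an estimated correlation), with Mbp at −0.52 ± 0.17. Granule cell markers had a median of −0.163, negative in 14 of 18 (0 and 0; adjusted p = 0.499 with an estimated correlation), with C1ql2 at −0.60 ± 0.18. Heat shock genes had a median of −0.111, negative in 14 of 19 (0 and 1 lower; adjusted p = 0.499 with an estimated correlation), with the chaperone Cryab at −0.47 ± 0.12. Nuclear-encoded oxidative phosphorylation genes had a median of −0.08, negative in 40 of 52 (0 and 0; adjusted p = 0.752 with an estimated correlation). Choroid plexus markers had a median of −0.931, negative in 20 of 20 (0 and 1 lower; adjusted p = 0.499 with an estimated correlation), with Sostdc1 at −1.49 ± 0.36. Ependymal markers had a median of −0.505, negative in 8 of 9 (0 and 0; adjusted p = 0.499 with an estimated correlation).

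Higher at 15 weeks were cholesterol synthesis genes, with a median of 0.131, positive in 18 of 23 (0 over all genes and 0 adjusted over the list alone; adjusted p = 0.65 with an estimated correlation). Squalene epoxidase, Sqle, stood at 0.31 ± 0.14. Neocortical markers had a median of 0.204, positive in 12 of 14 (0 and 0; adjusted p = 0.499 with an estimated correlation), with Cplx3 at 0.76 ± 0.23. Myeloid markers had a median of 0.422, positive in 6 of 8 (0 and 0; adjusted p = 0.528 with an estimated correlation), with Cd163 at 0.77 ± 0.27 (0.48 with TPM), and stood at −1.01 in nTg_15w_2. Over the alternatives the highest adjusted p of the 10 called lists lay between 0.33 and 0.862.

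Within the 15-week batch the control is 1 nTg library, assumed to vary like the other groups, so the list medians against it are given as values and show no call. They were −0.454 for activity-regulated, −0.364 for oligodendrocyte, −0.244 for granule cell, −0.468 for choroid plexus and 0.154 for neocortical genes, and 0.955 for myeloid markers, which stood at −1.01 in that library itself. They were 0.06 for cholesterol, −0.189 for ependymal, −0.105 for heat shock and −0.041 for oxidative phosphorylation genes. With an estimated correlation the adjusted p of these 10 lists lay between 0.118 and 0.932. Calls at 15 weeks were lost for heat shock without Tg_15w_2 (−0.107) or nTg_24w_1 (−0.048). They were lost for oxidative phosphorylation without Tg_15w_2 (−0.003) or nTg_24w_3 (−0.053), and for granule cells without nTg_15w_2 (−0.129) or nTg_24w_3 (−0.123). The cholesterol call was lost without nTg_24w_3 (0.073) and the myeloid call without Tg_15w_2 (0.271) or nTg_15w_2 (0.249). With calls kept, the oxidative phosphorylation median was −0.133 without Tg_15w_3 and −0.137 without nTg_24w_1. The myeloid median was 0.271 without Tg_24w_2, 0.273 without Tg_24w_3 and 0.201 without Tg_15w_1. Without both doubted libraries the heat shock call was lost (−0.045), and the choroid plexus median was −0.62 and the oxidative phosphorylation median −0.134.

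The third comparison set Tg at 24 weeks, after plaques have formed, against nTg (3 against 3 libraries). Of 17457 genes 23 passed the threshold, 9 higher and 14 lower, with 2273 at an unadjusted p under 0.05. Penk, the precursor of the enkephalin peptides (chromosome 4, 4133531 to 4138819), rose from 24.1 ± 3.49 CPM in nTg (SD, n = 3) to 128.5 ± 35.2 CPM in Tg (n = 3), a log2 fold change of 2.41 ± 0.20 (SE, edgeR adjusted p = 0.000386). Rprm, a cell cycle inhibitor that depends on p53 (chromosome 2, 54084093 to 54085552), rose by 1.80 ± 0.17 (edgeR adjusted p = 0.000677). Drd1 (chromosome 13, 54051183 to 54055705) rose by 1.54 ± 0.20 (0.0121), and complement component C4b (chromosome 17, 34728380 to 34743882) by 0.93 ± 0.12 (0.0124). C4b has the near-identical neighbour C4a (0.53 ± 0.56, edgeR adjusted p = 0.713), and reads shared between them make its value uncertain. Bmp3 (2.17 ± 0.35), Ecel1 (2.0 ± 0.29), the insulin-like growth factor binding protein Igfbp6 (1.87 ± 0.26), Ecm1 (1.68 ± 0.27) and the endothelial exchange factor Arhgef15 (0.98 ± 0.16) rose as well.

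Of the 14 genes that fell at 24 weeks, Dsp, a marker of dentate granule cells (chromosome 13, 38151294 to 38198577), went from 37.5 ± 5.46 to 8.71 ± 0.886 CPM (SD, n = 3 and 3). Its log2 fold change was −2.10 ± 0.18 (SE, edgeR adjusted p = 0.000386). Tdo2, tryptophan dioxygenase, another granule cell marker, fell by 1.93 ± 0.26 (edgeR adjusted p = 0.0124), and Pdyn, the precursor of the dynorphin peptides, by 1.35 ± 0.17 (0.0124). The activity-regulated genes Fos (−2.34 ± 0.26, chromosome 12, 85473890 to 85477273), Arc (−1.38 ± 0.21), Nr4a1 (−1.13 ± 0.17) and Egr1 (−1.07 ± 0.17) fell. So did Rtl3 (−2.68 ± 0.40), the protocadherin Fat4 (−1.33 ± 0.21), Fam160a1 (−1.17 ± 0.19) and Hectd2 (−1.13 ± 0.18). Sgk1, a kinase induced by glucocorticoids (−1.01 ± 0.14), Dusp6 (−0.81 ± 0.13) and Ppp1r16b (−0.73 ± 0.12) complete the 14. These 3 are outside the naming rule at 24 weeks and were chosen after their values were seen.

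Penk, Rprm, Dsp and Fos passed the threshold at 24 weeks in each of the 21 alternatives, and the same 4 genes were those called against the 2 nTg libraries of the 24-week batch in a fit that took the spread from all 9 libraries. None of the 4 passed in the fit of the 5 libraries of that batch alone, where Penk stood at 2.48, Rprm at 1.79, Dsp at −2.11 and Fos at −2.31. The count of 23 became 11 without Tg_24w_1, 16 without Tg_24w_2 and 36 without Tg_24w_3. It became 12, 13 and 12 without Tg_15w_1, Tg_15w_2 and Tg_15w_3, and 7, 4 and 6 without nTg_24w_1, nTg_15w_2 and nTg_24w_3. Drd1 did not pass without nTg_15w_2 (1.42) or nTg_24w_3 (1.5), nor did Pdyn (−1.32 and −1.25) or Sgk1 (−0.98 and −0.97). C4b did not pass without Tg_24w_2 (0.84), nTg_24w_1 (0.89), nTg_15w_2 (0.92) or nTg_24w_3 (1.0). The remaining genes lost their calls without 3 to 9 of the 9 libraries, Fam160a1 without any of them (−1.29 to −1.09). The count was 218 with DESeq2, 238 with limma voom with quality weights, 83 with a covariate of Xist against Y-linked expression and 107 (29 higher, 78 lower) without both doubted libraries, in each case with all 23 genes kept. Without both Bmp3 stood at 1.44. All 23 had the same sign in Tg at 15 weeks. Simulations of unchanged groups against the same 3 nTg libraries gave a median of 21 and a highest value of 23 in 100 runs. The simulated genes were picked by log2 CPM difference relative to spread and not by edgeR, so these counts rest on unlike rules. The differences of mean log2 CPM at 15 and at 24 weeks had a correlation of 0.356 across genes, against a simulated 0.502. Their covariance was 0.0403, against a simulated 0.0509. With Tg of each age set against nTg of its own batch, no control was shared. There 22 of the 23 had the same sign, and edgeR's log2 fold changes had a correlation of 0.0566 and a covariance of 0.0106. The 23 were picked by a contrast that holds nTg_15w_2, the control at 15 weeks here, so the selection itself favours a shared sign. Genes are not independent replicates, and the control at 15 weeks is then 1 library.

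**Figure D3:**
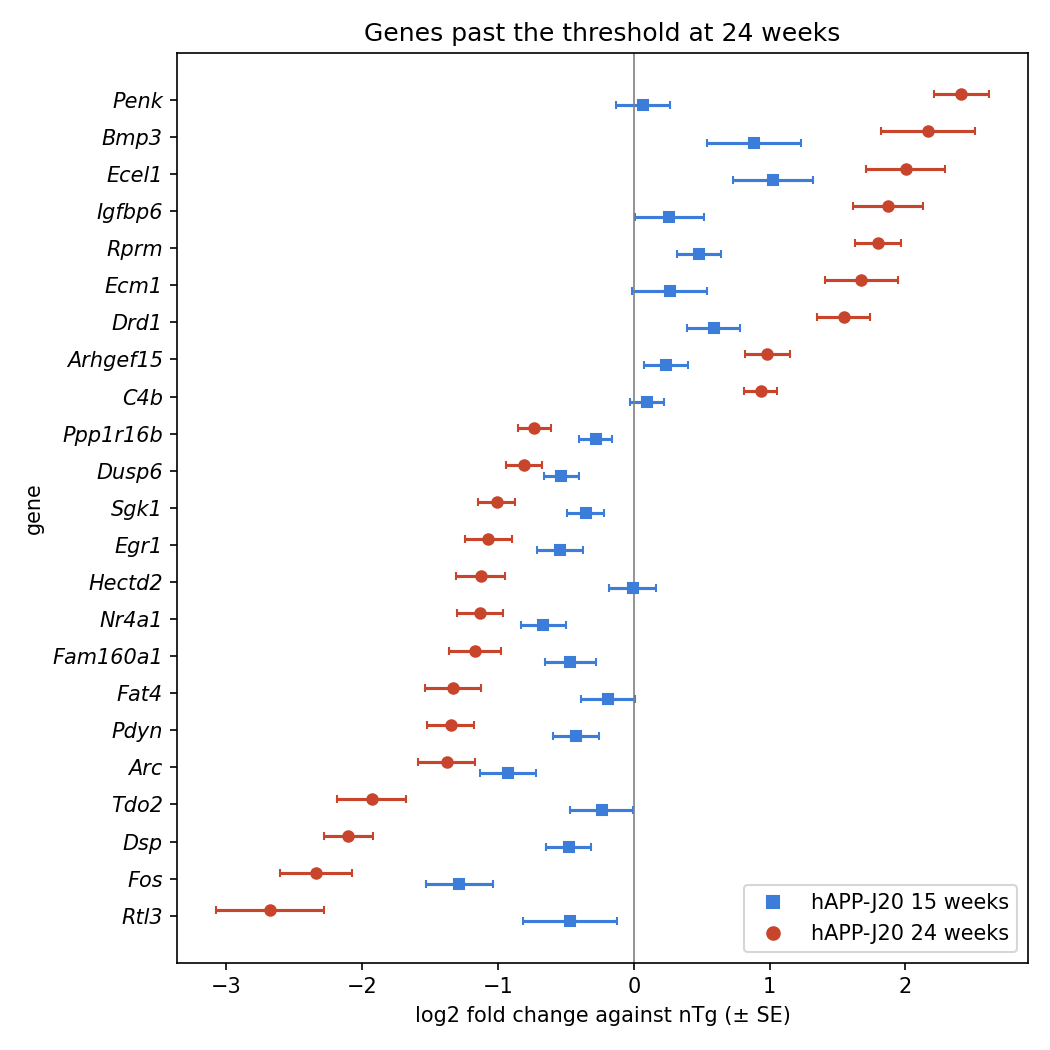
Log2 fold change against nTg ± SE (x axis) of the 23 genes past the threshold at 24 weeks (y axis), with Tg at 24 weeks as red circles and Tg at 15 weeks as blue squares. Values at 24 weeks run from −2.68 (Rtl3) to 2.41 (Penk), and no gene passed the threshold at 15 weeks.

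**Figure D4:**
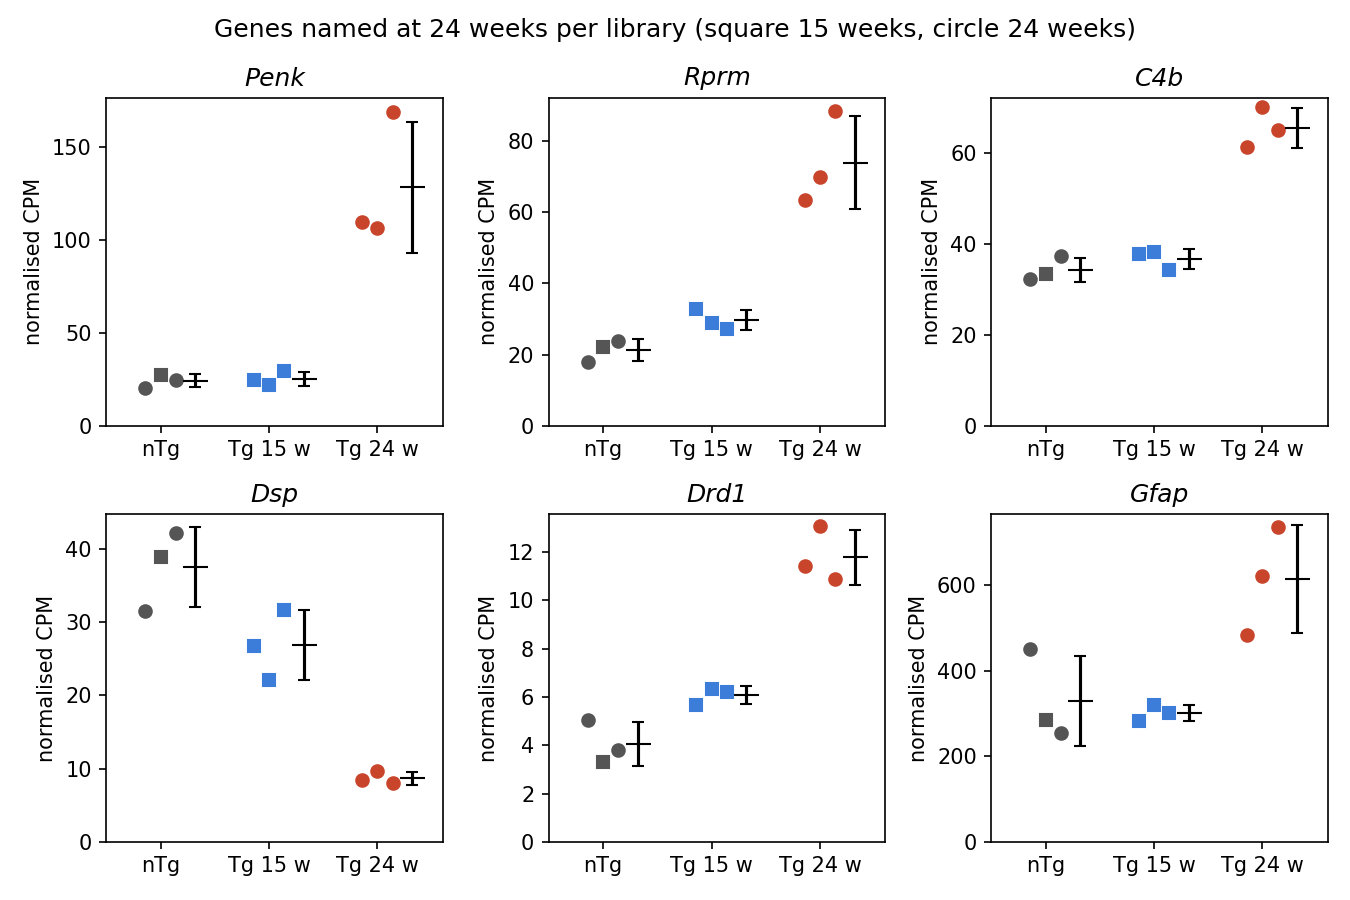
Normalised CPM (y axis, from 0) of Penk, Rprm, C4b, Dsp, Drd1 and Gfap in nTg, Tg at 15 weeks and Tg at 24 weeks (x axis); each point is 1 library (square 15 weeks, circle 24 weeks), and the black bars are mean ± SD of 3 libraries. Penk lies between 106.57 and 169.16 CPM in Tg at 24 weeks and between 20.38 and 29.31 CPM in the other 6 libraries, and Gfap did not pass the threshold.

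Among the neuronal lists at 24 weeks, activity-regulated genes fell by a median of −0.636, negative in 23 of 28 (camera adjusted p = 9.2e-13). The call gave adjusted p = 0.366 with an estimated correlation and a range of 2.23e-16 to 0.366 over the alternatives, and fry gave adjusted p = 0.0202. Of the members 5 were lower over all genes, and 2 were higher and 18 lower adjusted over the list alone. Granule cell markers fell as a list by a median of −0.459, negative in 12 of 18 (adjusted p = 0.542 with an estimated correlation). Of these Dsp and Tdo2 were lower over all genes, and 2 members were higher and 8 lower adjusted over the list alone. Members went both ways: Prox1 stood at −0.80 ± 0.15 (edgeR adjusted p = 0.0646) and Rasl10a at 0.80 ± 0.14 (adjusted p = 0.0589; 0.49 with the GC and length offset).

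Seizure-associated neuropeptide and calcium-binding genes rose as a list at 24 weeks by a median of 0.171, positive in 16 of 20 (adjusted p = 0.669 with an estimated correlation). Penk was higher and Pdyn lower over all genes, and 5 members were higher and 1 lower adjusted over the list alone. Galanin (Gal) at 3.22 ± 0.75 and the neurokinin precursor Tac2 at 1.0 ± 0.24 did not pass, and Gal stood at 1.99 without Tg_24w_3 and 1.66 with voom. The call was lost without Tg_24w_3 (0.076) or nTg_24w_1 (0.047) and with the GC and length offset (0.102), and the median was −0.017 without both libraries. Striatal markers were not called (camera adjusted p = 0.164), although Penk and Drd1 are both in that list (2 higher over all genes, 2 adjusted over the list alone). The abundant striatal gene Ppp1r1b stood at 0.55 ± 0.29 and Pde10a at −0.64 ± 0.24, and without Tg_24w_3 they stood at 0.01 and −0.36 and with voom at 0.24 and −0.42. Ppp1r1b stood at 0.26 with the offset and 0.3 with TPM. Fry's test of change in either direction, which does not compare the list with other genes, gave adjusted p = 0.000111 for the striatal list.

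Among the glial and immune lists at 24 weeks, complement genes rose by a median of 0.498 (positive in 11 of 15), interferon response genes by 0.413 (25 of 26), disease-associated microglia genes by 0.14 (19 of 22) and reactive astrocyte genes by 0.375 (17 of 24). Each had adjusted p = 0.542 with an estimated correlation. Over all genes 1 complement gene was higher (C4b) and 0 of the other 3 lists, and adjusted over the list alone the counts were 6, 3, 3 and 1. Not past the threshold were C1qa (0.73 ± 0.19), Psmb9 (1.40 ± 0.33) and the microglial genes Gpnmb (1.28 ± 0.26) and Trem2 (0.61 ± 0.18). C1qa stood at 0.45 without Tg_24w_3, 0.34 without both doubted libraries and 0.39 with the GC and length offset, and Psmb9 at 0.89 with TPM. Gfap stood at 614.4 ± 126 CPM against 329.6 ± 106 CPM (0.90 ± 0.21, edgeR adjusted p = 0.169). The class I genes H2-K1 (0.56 ± 0.13) and H2-D1 (0.58 ± 0.14) belong to a family of similar sequences and are uncertain, and with the offset they stood at 0.36 and 0.38.

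The astrocyte marker list was not called at 24 weeks (median −0.006, camera adjusted p = 0.413; 0 members over all genes, 0 adjusted over the list alone). The glutamate transporter Slc1a2 stood at −0.36 ± 0.14, glutamine synthetase Glul at −0.41 ± 0.16 and S100b at 0.61 ± 0.23. With the GC and length offset Slc1a2 stood at −0.06. Glul and S100b stood at −0.26 and 0.2 without Tg_24w_3, −0.22 and 0.15 without both doubted libraries and −0.23 and 0.27 with voom. Genes of astrocyte lactate, glycogen and glutamate metabolism were not called either (−0.092, adjusted p = 0.145; 0 and 0). Insulin and IGF signalling genes were not called (median −0.059 with a mean of 0.003, adjusted p = 0.189). Of 38 members 0 passed over all genes, and 1 was higher and 2 lower adjusted over the list alone. The insulin receptor substrate Irs2 stood at −0.48 ± 0.12, the insulin receptor Insr at −0.47 ± 0.13 and the glucose transporter Slc2a4 at 1.03 ± 0.28. With the offset Insr stood at −0.19, and with TPM Slc2a4 stood at 0.66. Fry's test of change in either direction gave adjusted p = 0.00708 for the insulin list, with members going both ways.

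Cholesterol synthesis genes rose as a list at 24 weeks by a median of 0.388, positive in 21 of 23 (adjusted p = 0.542 with an estimated correlation). Over all genes 0 members passed, and 12 were higher adjusted over the list alone, with Fdft1 at 0.69 ± 0.15 and Dhcr7 at 0.46 ± 0.13. Glycolysis genes had a median of 0.185, positive in 14 of 18 (0 and 0; adjusted p = 0.669 with an estimated correlation), with Eno2 at 0.41 ± 0.15. Nuclear-encoded oxidative phosphorylation genes had a median of 0.14, positive in 42 of 52 (0 and 0; adjusted p = 0.676 with an estimated correlation), with Cox4i1 at 0.52 ± 0.19 (0.28 without Tg_24w_3, 0.22 without both doubted libraries and 0.17 with the GC and length offset). Meningeal and fibroblast markers had a median of 0.623, positive in 11 of 14 (0 and 3 higher; adjusted p = 0.669 with an estimated correlation), with Col3a1 at 1.71 ± 0.36 (1.07 with TPM), and stood at −0.872 in nTg_15w_2. Choroid plexus markers had a median of −0.39, negative in 19 of 20 (0 and 0, adjusted p = 0.676 with an estimated correlation). In nTg_24w_1 they stood 1.05 above the median of the other libraries. Oligodendrocyte genes had a median of −0.288, negative in 15 of 20 (0 and 0; adjusted p = 0.669 with an estimated correlation), with Mobp at −0.49 ± 0.18 (−0.23 without both doubted libraries and with voom). Over the alternatives the highest adjusted p of the 13 called lists lay between 0.366 and 0.965. With the GC and length offset the glycolysis (0.059) and disease-associated microglia lists (0.09) lost their calls, the oxidative phosphorylation median became −0.045, and the complement median became 0.251 with its call kept.

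Against the 2 nTg libraries of the 24-week batch the glycolysis (0.188), oxidative phosphorylation (0.127), meningeal (0.371) and reactive astrocyte lists (0.198) lost their calls at 24 weeks, and the other 9 kept theirs with the preset correlation. The median of disease-associated microglia genes was 0.235 there, and with an estimated correlation the adjusted p of the 13 lists lay between 0.671 and 0.742. Without both doubted libraries the choroid plexus (−0.437) and oxidative phosphorylation calls (0.033) were lost, and the reactive astrocyte median was 0.205 and the complement median 0.324. The glycolysis call was lost without Tg_24w_1 (0.137), Tg_24w_2 (0.095), nTg_15w_2 (0.188) or nTg_24w_3 (0.209). The oxidative phosphorylation call was lost without Tg_24w_2 (0.137), Tg_24w_3 (0.053), nTg_24w_1 (0.105) or nTg_15w_2 (0.128), and its median was 0.219 without Tg_24w_1 and 0.215 without nTg_24w_3. The choroid plexus call was lost without Tg_24w_2 (−0.013) or nTg_24w_1 (−0.157), and its median was −0.673 without Tg_24w_1 or Tg_24w_3. The oligodendrocyte call was lost without Tg_24w_2 (−0.175), and the meningeal (0.371) and reactive astrocyte calls (0.253) without nTg_15w_2. With calls kept, the complement median was 0.319 without Tg_24w_3. That of disease-associated microglia was 0.328 without Tg_24w_2, 0.229 without nTg_24w_1, 0.241 without nTg_15w_2 and 0.352 without nTg_24w_3.

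The fourth comparison, named in the series' design, set Tg at 24 weeks against Tg at 15 weeks (3 against 3 libraries), where age and batch coincide. Xist was expressed without Ddx3y in Tg_15w_1 and Tg_15w_3, and at 24 weeks in Tg_24w_3 only. The apparent sex of the animals was therefore unbalanced between the ages. Penk rose from 25.3 ± 3.74 to 128.5 ± 35.2 CPM (SD, n = 3 and 3), a log2 fold change of 2.34 ± 0.20 (SE, edgeR adjusted p = 0.000848), and Rprm rose by 1.32 ± 0.16 (0.0164). Rasl10a, a small GTPase gene of granule cells, rose by 1.05 ± 0.15 (edgeR adjusted p = 0.0374), Tmc6 by 1.62 ± 0.24 (0.0489) and C4b, uncertain beside C4a, by 0.84 ± 0.12 (0.0489). Dsp went from 26.9 ± 4.81 to 8.71 ± 0.886 CPM, a log2 fold change of −1.62 ± 0.18 (edgeR adjusted p = 0.00644). These were the 6 genes past the threshold, 5 higher and 1 lower, with 2645 at an unadjusted p under 0.05. The count became 8, 7 and 14 without Tg_24w_1, Tg_24w_2 and Tg_24w_3, and 1, 2 and 1 without Tg_15w_1, Tg_15w_2 and Tg_15w_3. It became 3, 2 and 5 without nTg_24w_1, nTg_15w_2 and nTg_24w_3, which enter only through the spread and the filter. Penk passed with each library left out, and Dsp did not pass without Tg_15w_1 (−1.65) or Tg_15w_3 (−1.48), with the spread of the 6 compared libraries or with TPM (−1.47). Rprm (1.16 to 1.39) did not pass without nTg_15w_2 or any Tg library at 15 weeks, and Rasl10a (0.96 to 1.11) did not without these 4, Tg_24w_2 or nTg_24w_1. Tmc6 (1.40 to 1.82) passed only without Tg_24w_2 or Tg_24w_3, and C4b (0.74 to 0.87) only without Tg_24w_3. With the GC and length offset Penk and Dsp stayed past the threshold and the other 4 did not. There Rasl10a went from 1.05 ± 0.15 to 0.67 ± 0.17, Rprm from 1.32 ± 0.16 to 1.0 ± 0.14 and Tmc6 from 1.62 ± 0.24 to 1.43 ± 0.24, while C4b went from 0.84 ± 0.12 to 0.87 ± 0.13 (SE). With a covariate of Xist against Y-linked expression 700 genes passed, 567 higher and 133 lower, and without both doubted libraries 71 passed, 30 higher and 41 lower.

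Of the 38 lists, camera called 12 as higher and 4 as lower at 24 than at 15 weeks in Tg. Disease-associated microglia genes rose as a list by a median of 0.377, positive in 17 of 22 (0 over all genes and 10 adjusted over the list alone; adjusted p = 0.553 with an estimated correlation). Gpnmb stood at 1.38 ± 0.26 and Cd63 at 1.02 ± 0.22 (0.66 without Tg_24w_3, 0.65 also without nTg_24w_1). Interferon response genes rose by a median of 0.293 (23 of 26; 0 and 6 members), complement genes by 0.442 (13 of 15; 1, C4b, and 5) and reactive astrocyte genes by 0.313 (20 of 24; 0 and 3), with Gfap at 1.02 ± 0.22. Each of these 3 had adjusted p = 0.553 with an estimated correlation. Glycolysis, heat shock and oxidative phosphorylation genes rose as lists too, each with adjusted p = 0.553 with an estimated correlation. Glycolysis genes had a median of 0.244 (16 of 18, 0 and 3 members), with Eno1 at 0.46 ± 0.13, and heat shock genes one of 0.203 (16 of 19, 0 and 0), with Cryab at 0.40 ± 0.12. Oxidative phosphorylation genes had a median of 0.239 (45 of 52, 0 and 0), with Cox4i1 at 0.66 ± 0.19 (0.42 without Tg_24w_3). With the GC and length offset Eno1 stood at 0.19, Cryab at 0.11 and Cox4i1 at 0.24.

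Cholesterol synthesis, seizure-associated, endothelial and meningeal genes were higher as lists at 24 than at 15 weeks, each with adjusted p = 0.557 with an estimated correlation. Cholesterol synthesis genes had a median of 0.228 (19 of 23, 0 members over all genes and 0 adjusted over the list alone). Seizure-associated genes had one of 0.299 (15 of 20), with Penk past the threshold over all genes, 4 higher and 1 lower adjusted over the list alone, and the calcium-binding gene Calb2 at 0.77 ± 0.13. Endothelial markers had a median of 0.338 (13 of 15, 0 and 1), with the tight junction gene Cldn5 at 1.32 ± 0.34 (0.77 without Tg_24w_3, 0.76 also without nTg_24w_1), and meningeal markers one of 0.391 (12 of 14, 0 and 2), with Col3a1 at 1.82 ± 0.36 (1.14 with TPM). Choroid plexus markers were higher by 0.335 (20 of 20, 0 and 0; adjusted p = 0.711 with an estimated correlation), and stood at −1.08 in Tg_24w_2 and −1.09 in Tg_15w_3.

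Activity-regulated, interneuron, glutamatergic and neocortical genes fell as lists between 15 and 24 weeks, each with adjusted p = 0.553 with an estimated correlation. Activity-regulated genes had a median of −0.259, negative in 21 of 28 (0 members over all genes, 1 higher and 3 lower adjusted over the list alone). GABAergic interneuron genes had a median of −0.262 (negative in 15 of 19, 0 and 0), with neuropeptide Y (Npy) at 0.95 ± 0.30 the other way (0.39 without Tg_24w_3, 0.49 with voom and 0.55 with the GC and length offset). Glutamatergic postsynapse genes had a median of −0.139 (23 of 30, 0 and 0), with the NMDA receptor subunit Grin2a at −0.48 ± 0.15 (−0.13 with the offset). Neocortical markers had a median of −0.262 (11 of 14, 0 and 2 lower), with the protocadherin Pcdh20 at −0.66 ± 0.14. The astrocyte list was not called (median 0.028 and mean 0.003 with camera's direction downward, adjusted p = 0.719), nor was the insulin list (median −0.109 and mean 0.022, adjusted p = 0.535; fry in either direction, adjusted p = 0.0235). Over the alternatives the highest adjusted p of the 16 called lists lay between 0.553 and 0.711. With the GC and length offset the oxidative phosphorylation (0.017), glutamatergic (0.009) and seizure-associated lists (0.086) lost their calls. With it the complement (0.19), disease-associated microglia (0.171) and glycolysis medians (0.133) moved by over 1.5 times with calls kept.

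Calls between the ages were also lost when 1 library was left out, in part with medians little changed. The choroid plexus call was lost without Tg_24w_1 (0.094), Tg_24w_3 (0.179) or Tg_15w_3 (0.128), and its median was 0.699 without Tg_24w_2. The endothelial call was lost without Tg_24w_3 (0.198), Tg_15w_2 (0.182) or Tg_15w_3 (0.227), and the interneuron call without Tg_24w_3 (−0.144), Tg_15w_2 (−0.205) or Tg_15w_3 (−0.271). The heat shock call was lost without Tg_24w_1 (0.202) or Tg_15w_3 (0.205), and its median was 0.127 without Tg_24w_2. The glutamatergic call was lost without Tg_24w_1 (−0.181) or Tg_15w_2 (−0.088). Calls were also lost for cholesterol without Tg_24w_2 (0.163), seizure-associated genes without Tg_24w_3 (0.156), glycolysis without Tg_15w_1 (0.136) and meninges without Tg_15w_3 (0.205). With calls kept, the neocortical median was −0.423 and the reactive astrocyte median 0.18 without Tg_24w_1, and the cholesterol median was 0.144 without Tg_24w_3. The oxidative phosphorylation median was 0.138 without Tg_24w_3 and 0.141 without Tg_15w_2, and the interferon median 0.504 without Tg_15w_1. Without both doubted libraries calls were lost for cholesterol (0.134), choroid plexus (0.168), endothelial (0.188), interneuron (−0.154) and seizure-associated genes (0.146), and the meningeal median was 0.252 and the oxidative phosphorylation median 0.127.

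**Figure D5:**
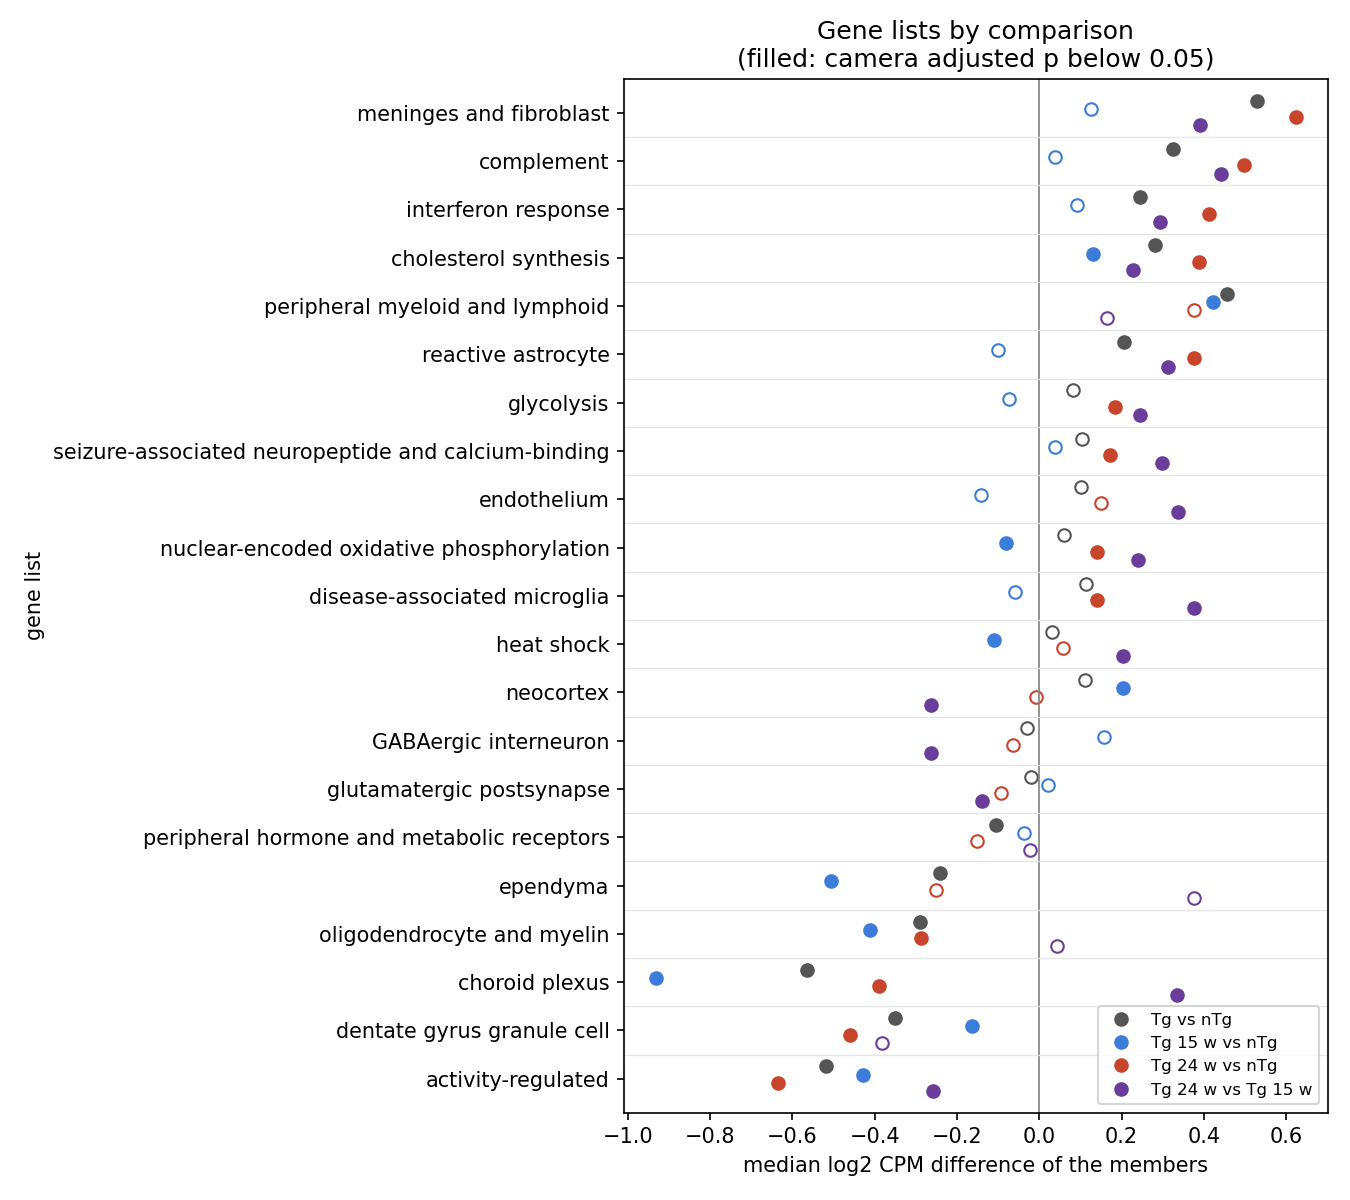
Median log2 CPM difference (x axis) of the members of the 21 gene lists that camera called in at least 1 comparison (y axis), by comparison: grey Tg against nTg, blue Tg at 15 weeks against nTg, red Tg at 24 weeks against nTg, purple Tg at 24 against 15 weeks; filled points have a camera adjusted p below 0.05. Activity-regulated genes are at −0.518, −0.428, −0.636 and −0.259, filled in each comparison.

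The last comparison asked whether the genotype difference itself changed with age, with each age set against its own nTg libraries. Penk had the smallest p, with a difference between the ages of 2.62 ± 0.35 (SE, edgeR adjusted p = 0.123). The count was 0 of 19574 genes with edgeR, with 408 at an unadjusted p under 0.05 where chance gives 979. DESeq2 called 1 and limma voom with quality weights 1, and edgeR called 1 without Tg_24w_3. The test rests on 1 nTg library at 15 weeks, without which it could not be fitted.

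In all, 17 of the 38 lists were called in no comparison. Among cell markers their smallest camera adjusted p was 0.194 for CA1 pyramidal cells, 0.52 for CA3 pyramidal cells, 0.194 for subiculum and CA2 and 0.0945 for neurogenesis. It was 0.403 for astrocytes, 0.223 for homeostatic microglia, 0.0607 for oligodendrocyte precursors and 0.0899 for pericytes. It was 0.164 for striatum, 0.311 for thalamus and habenula and 0.063 for blood. For pathways it was 0.386 for amyloid processing, 0.145 for astrocyte lactate, glycogen and glutamate metabolism and 0.188 for insulin and IGF signalling. It was 0.674 for mitochondrially encoded genes, 0.283 for presynaptic genes and 0.43 for the unfolded protein response.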

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

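The fits with 1 library left out and against age-matched nTg were alternatives fixed beforehand. Their use as tests of single libraries and of the batch was chosen after the results they bear on had been seen. So were the tests of GC content, of striatal tissue and of other groupings of the libraries. For 6 genes the effect against the same nTg libraries differed between the ages of the Tg mice, by the edgeR test of Tg at 24 against Tg at 15 weeks. The effect at 24 weeks minus that at 15 weeks was 2.34 for Penk, 1.32 for Rprm, −1.62 for Dsp, 0.84 for C4b, 1.05 for Rasl10a and 1.62 for Tmc6 (log2, 3 libraries each). Of 21 alternatives Penk passed in 21, Dsp in 17, Rprm in 14, Rasl10a in 10, Tmc6 in 9 and C4b in 6. In nTg the change from 15 to 24 weeks, which is also a change of batch, was −0.29 ± 0.29 for Penk, −0.1 ± 0.26 for Rprm, −0.09 ± 0.27 for Dsp, 0.05 ± 0.21 for C4b, −0.3 ± 0.22 for Rasl10a and 0.32 ± 0.36 for Tmc6 (SE, 2 against 1 libraries, with the 1 library at 15 weeks assumed to vary like the other groups). The change in Tg minus that in nTg had an edgeR adjusted p of 0.123 for Penk (2.62 ± 0.35) and 1 for each of the other 5. A genotype difference equal at both ages, together with a difference between batches, therefore cannot be told apart from a change with age in Tg for these genes, since nTg at 15 weeks is 1 library.

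Of the 23 genes changed in Tg at 24 weeks, 22 passed without Tg_24w_3, the library apart from the others on the first principal component. These 22 calls did not need that library. The 23 were picked with it in the fit, where a gene changed in it alone would rarely pass. A trend with GC content or transcript length as the whole cause is argued against by the 20 of 23 that passed with the offset, where the calls that ended were Ecm1 (1.68 ± 0.27 to 1.43 ± 0.28) and Ppp1r16b (−0.73 ± 0.12 to −0.55 ± 0.15), whose change shrank, and Arhgef15, which stayed at 0.98 (SE 0.16 to 0.17) and missed the threshold at an adjusted p of 0.0514 (range 0.000338 to 0.276). Within the 24-week batch the changes of all 23 genes were at least 0.92 times those against all nTg and over 2 standard errors. Of these genes 4 passed there with the spread of all 9 libraries. The 23 were picked by a contrast that holds these same libraries. A gene whose nTg libraries differed between the batches would rarely be among them. The ratio therefore cannot decide whether the batch plays a part. Striatal tissue in the Tg samples that raised all striatal genes alike would bring their median near Drd1, at 1.54. The median of the 14 striatal markers, Penk and Drd1 among them, was 0.27. Below Drd1 the markers ran from −0.64 (Pde10a) to 0.55 (Ppp1r1b). The 95% interval of the median, −0.34 to 0.55, takes genes as independent replicates, which they are not. Tissue that raised each gene by its own share is not covered, since the markers' levels in hippocampus were not weighed. A response of the hippocampus to the transgene at this age remains open as a hypothesis and is untested, and genotype labels that the transgene could not check remain open too.

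In Tg against nTg over both ages 0 genes passed, so that any split gives as many (84 of 84), which says nothing about chance; the highest other split gave 3 (edgeR; 941 genes at an unadjusted p under 0.05, 35 called by DESeq2). The split with 3 genes set the 3 Tg libraries at 24 weeks apart from the other 6. With age as a term, that split compared Tg with nTg at 24 weeks, the real genotype difference at that age. It is therefore no neutral split. The 3 comparisons of 3 against 3 libraries have 10 splits each, too few for a share under 0.05. At 15 weeks the real count was 0 and the highest other 0, and a count of 0 is matched by all 10 of 10 splits whatever they hold. At 24 weeks the real count was 23 and the highest other 0 (1 of 10), and between ages the real count was 6 and the highest other 0 (1 of 10).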

How the results depend on the processing

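The fit without 2 doubted libraries, the GC and length offset, limma voom with quality weights and limma on TPM were chosen after the data had been seen. Of the named genes' values, 1299 of 1458 with 1 library left out and 1647 of 1942 under other alternatives kept direction and side of the threshold; of the called lists' values, 400 of 459 and 200 of 329 did. Genotype over both ages called 0 genes with edgeR, 35 with DESeq2, 135 with no filter, 1 with the Xist and Y covariate, 3 without both doubted libraries and 7 with voom, and 0 to 5 with 1 library left out. At 15 weeks the count of 0 became 2 with DESeq2, 65 with no filter and 5 with voom, and 0 to 0 with 1 library left out. At 24 weeks the count of 23 became 218 with DESeq2, 559 (354 higher, 205 lower) with no filter, 83 (39 higher, 44 lower) with the covariate, 107 (29 and 78) without both doubted libraries and 238 with voom, each keeping all 23. It became 4 against age-matched nTg and 5 with the spread of the 6 compared libraries, where fewer samples give the spread, 12 (10 kept) with TPM, and 4 to 36 with 1 library left out. Between ages the count of 6 became 284 (183 higher, 101 lower) with DESeq2, 701 (510 and 191) with no filter, 700 (567 and 133) with the covariate, 71 (30 higher, 41 lower) without both doubted libraries, 102 (64 and 38) with voom, 2 with 4 groups, 2 with the offset, 2 with TPM, 1 with the spread of the 6 libraries, and 1 to 14 with 1 library left out. The interaction's 0 became 1 with DESeq2, 17 with no filter, 4 with the covariate, 4 without both doubted libraries and 1 with voom, and 0 to 1 with 1 library left out; without nTg_15w_2 it gave no value. Where no cause is named, the cause was not tested. The median of all genes moved by over 0.1 only at 24 weeks with TPM, from 0.0273 to −0.0779.

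The lists called by camera numbered 12 for genotype (9 to 13 with 1 library left out), 10 at 15 weeks (7 to 13), 13 at 24 weeks (10 to 14) and 16 between ages (11 to 19). They numbered 0, 0, 0 and 0 with an estimated correlation and 1, 0, 1 and 0 with fry in 1 direction and 1, 0, 13 and 19 with fry in either direction, which test other hypotheses. Reversed values were as follows, and the cause was not tested. App for genotype was 0.02 and became 0 with RLE factors, 0 with DESeq2 and −0.08 with TPM, and −0.11 to 0.15 with 1 library left out. App at 15 weeks became −0.02 against age-matched nTg. App at 24 weeks was −0.06 and became 0.04 against age-matched nTg, 0.01 without both doubted libraries, 0.16 with the offset and 0 with voom, and −0.24 to 0.17 with 1 library left out. Between ages App became 0.01 with the offset, and −0.41 to 0.01 with 1 library left out. Zbtb20 at 24 weeks became 0.15 with the offset, and −1.15 to 0.06 with 1 library left out. Between ages Zbtb20 was 0.48 and became −0.47 without both doubted libraries and −0.33 with voom, and −0.46 to 0.75 with 1 library left out. At 24 weeks the seizure-associated median became −0.017 without both doubted libraries and the oxidative phosphorylation median −0.045 with the offset.

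No clear pairing of the samples by replicate number was seen, though correlations in groups this small cannot exclude it. Deviations of same-numbered Tg libraries at 24 and 15 weeks correlated at −0.11, 0.14 and −0.05, and those of other same-numbered libraries at −0.24 to 0.29. With the replicate number as a block the counts were 1 for genotype, 0 at 15 weeks, 15 at 24 weeks (14 kept) and 4 between ages; no blocked interaction was fitted.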

Other observations

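The tests of explanations here were chosen after the results they bear on had been seen, though leaving out each library was an alternative fixed beforehand. The list tests were fixed beforehand too. The list scores and their permutation tests are not named in that plan. Markers of dentate granule cells moved apart between 15 and 24 weeks in Tg. Dsp fell by 1.62 ± 0.18 and Rasl10a rose by 1.05 ± 0.15 (SE, edgeR, 3 against 3 libraries), though with the GC and length offset Rasl10a stood at 0.67 ± 0.17 and did not pass. Tdo2 stood at −1.69 ± 0.26 (edgeR adjusted p = 0.0517), C1ql2 at 1.13 ± 0.19 (0.0799) and Plk5 at 0.92 ± 0.16 (0.109), none of these past the threshold. The granule cell list was not called between ages (median −0.381, camera adjusted p = 0.0561; 1 member higher and 1 lower over all genes, 3 higher and 6 lower adjusted over the list alone). Neuropeptide genes stood at 2.39 ± 0.69 for Gal, 0.95 ± 0.30 for Npy and 0.63 ± 0.23 for Tac2 between the ages, and Pdyn at −0.92 ± 0.17, none past the threshold; without Tg_24w_3 Gal stood at 1.15 and Npy at 0.39, and with voom at 1.08 and 0.49. Xist at 7.33 CPM beside Ddx3y at 38.9 CPM was seen in nTg_24w_1 and in no other library. This library may be a mixed sample or hold reads of another library, which was not tested. Without it 7 genes passed at 24 weeks where 23 passed with it. The fall is not particular to this library, since the count was 4 without nTg_15w_2 and 6 without nTg_24w_3. Without both nTg_24w_1 and Tg_24w_3 it was 107, with all 23 kept.

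Activity-regulated genes were lower in Tg than in nTg over both ages, with a list score difference of −0.51 (n = 6 and 3). A single nTg library as the source is argued against by the smallest difference with each nTg library left out in turn, −0.44 (without nTg_24w_1). A trend with GC content or length is argued against by the median of the 28 genes with the offset, −0.552 against −0.518 without it. Fewer granule cells in the Tg samples may lower both lists: the activity score minus the granule cell score differed by −0.22 (exact two-sided permutation p = 0.131 over 84 splits), too uncertain for the cell share and the activity of the cells to be told apart. An effect of the transgene on neuronal activity remains open and is a hypothesis only.

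Nuclear-encoded oxidative phosphorylation genes were higher in Tg at 24 than at 15 weeks (median 0.239, 45 of 52 members). A trend with GC content or length between the libraries could account for this, since the median with the offset was 0.017. Tg_24w_3 alone is argued against by the median without it, 0.138, which stayed called. The correlation of each library's log2 deviation with GC content across genes was 0.379, 0.41 and 0.15 in Tg at 24 weeks and −0.572, −0.448 and 0.224 in Tg at 15 weeks; genes are not independent replicates. Against nTg of the same batch the median was 0.127 at 24 weeks (not called) and −0.041 at 15 weeks, where the control is 1 library, so a difference between the batches and a change with age both remain open.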
